A study of Rattus norvegicus with 14 samples.

How the data were processed

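CA3 tissue from 14 young male Long-Evans rats was profiled, 7 from a group trained in a maze with spatial cues and a platform that stayed in place (the learning group) and 7 from a control group whose platform moved between trials without informative cues. Each animal was put in its group, and given its replicate number, from the title of its sample. The labels call the samples biological replicates. Per the labels' protocols, total RNA was extracted with Trizol and RNeasy columns, labelled with biotin and hybridised at a core facility to Affymetrix RAE230A arrays, on which a probe set of short oligonucleotides measures a stretch of a transcript, usually near its 3' end.

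The deposited values are log2 expression levels, 1 column per array, for 15923 probe sets. The authors made them with GCRMA, per the submitters' processing notes. GCRMA is a method that corrects background by probe sequence, normalizes between arrays and summarises the probes of a set. Its version, its settings and the scale of the table are not given in the sources used here, and the log2 scale was inferred from the range and medians of the values. Such values compress differences near background, so fold changes of dim probe sets can be understated or amplified by the background model. Column means were 5.44 in both groups, column medians lay between 5.07 and 5.09, and no gene centring was seen. No scan date or slide was used here, so no batch could be tested. Arrays have no read depth, and the number of arrays limits the precision.

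Genes were taken from the GEO platform annotation of the array. It named 1 gene for 12789 probe sets and several for 312, which were left unnamed, and it did not list 2771. Symbols were updated through the Entrez ID against the RefSeq gene table of assembly GRCr8, where 12754 of the single-gene probe sets matched. No genome build is named for the array values, so no coordinates are given.

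The 57 Affymetrix control probe sets were left out of the tests, as were 6346 dim ones with a mean below the 40th percentile, a mean log2 level of 3.88. The remaining 9520 were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with learning minus control as the coefficient and no covariate, and p-values were adjusted by Benjamini-Hochberg over all of them. A probe set was called at an adjusted p under 0.05. "Rose" and "fell" are used only of called probe sets and of gene lists past the same threshold. Error values after ± are standard deviations over the 7 animals of a group unless called SE.

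Gene lists were tested with camera of limma, which asks whether a list's genes moved relative to the other genes, with a preset inter-gene correlation of 0.01. Each gene entered with its brightest probe set, lists needed 5 measured members, and the 20 pathway lists and 11 cell marker lists were adjusted separately. An estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Single values per array, such as a mean over markers, were compared by a two-sided exact permutation test over all 3432 assignments of the 14 arrays. Signal ratios between 3' and 5' control probe sets of Gapdh, beta-actin and hexokinase measured RNA integrity and amplification length. The bacterial and phage spike-in probe sets measured hybridization.

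The groups, the model, the filter, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 15 called genes per direction with the largest change, each by its probe set of lowest p, and 14 genes reported in any case by their brightest probe set. From each list that passed, or that is described, it took the 4 members with the lowest p and the 2 brightest. From each marker list it took the 2 brightest. Genes outside the rule are said to be so. List members called only at a probe set other than their brightest were outside it and were named after their values were seen.

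The alternatives chosen at that time were 3 other filters on dim probe sets, trended and robust variance moderation, array weights, quantile normalization, median centring, the replicate number as a block, the Gapdh ratio or the dentate marker level as covariate, each array left out, the mean of all probe sets per gene, the other probe sets of a named gene, the estimated correlation and fry. Alternatives added after the data were seen were leaving out 3 arrays that stood apart, the hexokinase ratio, the actin ratio, the spike-in level or the balance of dimmer and brighter probe sets as covariate, and 1 brightest probe set per gene. The procedure was tested on simulated data with the 9520 probe sets, 200 of them changed. It recovered 86% of those changed by 0.4 and 98% of those changed by 1 on the log2 scale, with 6.60% false calls. With no effect it called 0 probe sets and 1 gene list. The simulated probe sets varied independently of each other, without the variation that genes and arrays share in real data. These rates therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.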

Results

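RNA of the hippocampal subfield CA3, whose pyramidal neurons are densely connected with each other, was measured in 14 rats, 1 array per animal and 7 animals per group. All rats, 3 to 4 months old, had already learned a standard water maze. After 2 to 3 weeks they swam 8 trials, 8 min apart, in an unfamiliar maze. Rats of the learning group had spatial cues and a visible platform that stayed in place, and control rats had a visible platform that moved and no informative cues. A probe trial of 90 s without a platform came 1 h later, and the tissue was taken directly afterwards. The comparison asks whether rapid encoding of a new place alters CA3 transcripts, those tied to synaptic plasticity in particular. Cues and platform movement differed along with it, so their effects cannot be told apart from that of encoding. Correlations between arrays over the tested probe sets ran from 0.983 to 0.995, and no pair of columns was identical.

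The largest increases at single probe sets were in Grin2a, Map2 and Tmod2, genes of a glutamate receptor and of the neuronal cytoskeleton. That of Map2 was not seen at its brighter probe set. Grin2a, an NMDA receptor subunit, had a log2 level of 5.36 ± 0.51 in the learning group and 3.88 ± 0.40 in the control group (n = 7 each), a 2.78-fold difference (adjusted p = 0.00323). Its control level lay at the dim cutoff of 3.88 and is not shown to be above background, so the size of that difference is uncertain. Map2, the microtubule protein of dendrites, was 2.57-fold higher (9.19 ± 0.63 against 7.82 ± 0.31, adjusted p = 0.00736), and Tmod2, the neuronal protein that caps actin filaments, was 2.47-fold higher (7.37 ± 0.26 against 6.07 ± 0.50, adjusted p = 0.00323). The largest decrease was in Ttr, the thyroid hormone carrier made mainly by the choroid plexus, which was 4.25-fold lower (5.46 ± 0.53 against 7.55 ± 1.05, adjusted p = 0.0124). In each of these genes all 7 learning animals lay on the same side of the control mean.

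Of the 9520 probe sets tested with limma, 319 passed the adjusted threshold, 243 higher and 76 lower in the learning group. They named 267 genes, 199 higher and 68 lower. The median size of a called change was 0.37 on the log2 scale, and 68 called probe sets changed at least 1.5-fold, 64 of them upward. In 200 probe sets the groups did not overlap, where chance gives 5.55. Unadjusted p-values lay under 0.05 for 1898 probe sets, 889 higher and 1009 lower, against 476 by chance. Of the 56 called genes taken by the rule from the largest changes, the fixed genes, the lists that passed and the immediate early genes, 12 were still called with the Gapdh 3'/5' ratio as covariate, 1 with the dentate marker level, 21 without 3 arrays that stood apart and 0 with the balance of dimmer and brighter probe sets, and all 56 kept their direction in each. The count fell to 39 with the Gapdh 3'/5' ratio as covariate, to 3 with the dentate marker level, to 0 with the balance of dimmer and brighter probe sets (853 at unadjusted p under 0.05), to 177 with the hexokinase ratio and to 143 with the spike-in level, and was 158 without a filter, 132 with 1 probe set per gene and 105 without 3 arrays that stood apart. The probe sets called higher had a median log2 fold change of 0.44 (median SE 0.0894). It was 0.38 with the Gapdh ratio as covariate (median SE 0.10), 0.35 with the dentate level (0.104), 0.24 with the probe set balance (0.105), 0.40 with the hexokinase ratio (0.0812), 0.49 with the spike-in level (0.109) and 0.36 without the 3 arrays (0.0771). All 319 kept their sign in each of these, except 1 with the probe set balance, where 318 did. That balance was built from tested probe sets, some of them of called genes, and correlated with group at 0.75. Adjusting for it can therefore also take out a real difference between the groups. Calls of probe sets or lists lost with it do not decide between the 2. The count also dropped by more than 1.5 times without control replicate 1 (163), 2 (166) or 3 (167) and without learning replicate 3 (188), 4 (164), 6 (171) or 7 (188).

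Among the other genes with the largest increases at their called probe sets, Gria3, an AMPA receptor subunit, rose by a log2 fold change of 1.19 (SE 0.15, adjusted p = 0.00248). Further increases were found for the RNA helicase Ddx6 (1.14), the astrocytic water channel Aqp4 (1.10), the microtubule protein Map1b (1.06) and the GABA-A receptor subunit Gabrg1 (1.01). Mgll, a lipase that degrades an endocannabinoid, rose by 1.01 and Cnr1, the main cannabinoid receptor of neurons, by 0.97. Increases of 0.87 to 0.91 were found for the transcription factor Atf2, the actin motor Myo5a, the RNA-binding protein Zranb2, Wdr7 and the RNA-editing enzyme Adarb1. Adjusted p-values of these genes lay between 0.00248 (Zranb2) and 0.0415 (Mgll).

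Decreases other than that of Ttr were smaller. Igsf1, a membrane protein of the immunoglobulin family, changed by -0.83 (SE 0.19, adjusted p = 0.0342), and Tpd52l1 by -0.82 (SE 0.11, adjusted p = 0.00323). The endothelial adhesion receptor Adgrl4 (-0.60), Akip1 (-0.49), Bnip2 (-0.49), Tmem47 (-0.48), the exchange factor Spata13 (-0.44) and Txnip (-0.42), an inhibitor of thioredoxin, fell as well. Smaller decreases were found in Rmdn3 (-0.37), Mtmr10 (-0.33), Unc119b (-0.32), Clic4 (-0.30), the mitophagy receptor Bnip3l (-0.30) and the NF-kappaB inhibitor Nfkbib (-0.29). Adjusted p-values of these ranged from 0.00323 for Unc119b to 0.0418 for Nfkbib.

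**Figure D1:**
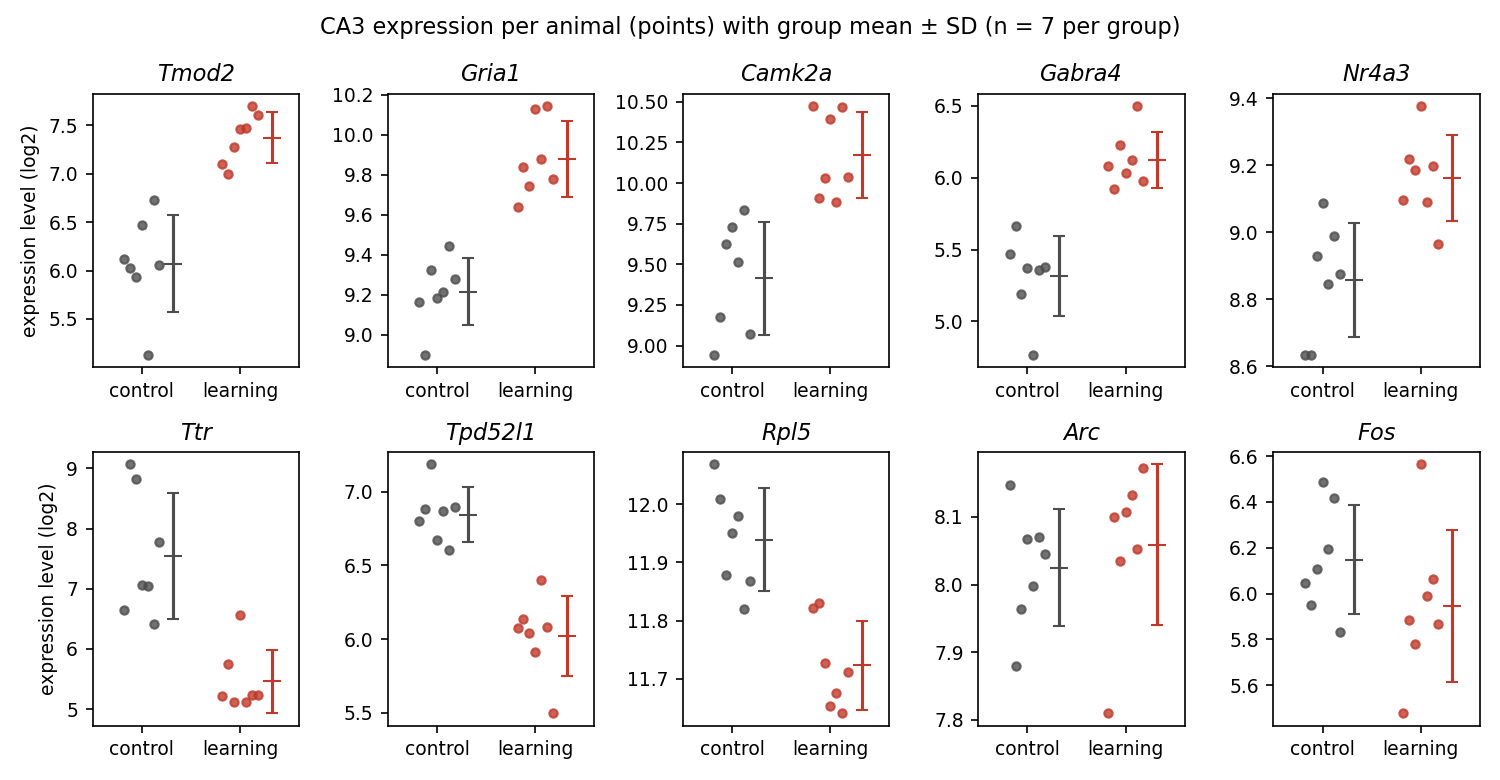
Log2 expression levels of 10 genes in CA3, 1 point per animal (7 control, 7 learning), with the group mean and standard deviation as a bar beside the points and a separate vertical scale in each panel. Tmod2, Gria1, Camk2a, Gabra4 and Tpd52l1 show no overlap between the groups, Nr4a3, Ttr and Rpl5 passed the test with overlapping groups, and Arc and Fos did not pass.

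For many genes the increase was seen at only part of their probe sets. In 95 genes the called probe set was a dimmer one of several, with a median log2 fold change of 0.44, while the brightest probe set of the same genes had a median of 0.03 and was itself called in 5 of them. The reverse comparison also gave a smaller change at the other probe set: in 30 genes called higher by their brightest probe set the median was 0.35 there and 0.10 at the next brightest. Map2 rose by 1.36 at the called probe set and had 0.05 at its brighter one (adjusted p = 0.692). The brighter probe sets of Gria3 (0.05), Map1b (0.07), Cnr1 (-0.02), Aqp4 (-0.05), Ddx6 (-0.08), Zranb2 (-0.03), Adarb1 (-0.04) and Mgll (-0.02) did not pass either. Tmod2 was called at each of its 3 probe sets, with log2 fold changes of 1.31, 0.80 and 0.52, and Grin2a had 0.23 at its other probe set (adjusted p = 0.102). In the other direction, Clic4 had 0.13 and 0.40 and Bnip3l 0.04 at probe sets that were not called. Of the calls adjusted over all 9520 probe sets, 109 higher and 67 lower ones were the brightest of 6836 genes, and 36.1% of these genes had a fold change above 0 there. Tested with that 1 probe set per gene and adjusted over those alone, 84 genes were higher and 48 lower. At an unadjusted p under 0.05 these were 436 higher and 855 lower, and under 0.005 they were 174 and 159.

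**Figure D2:**
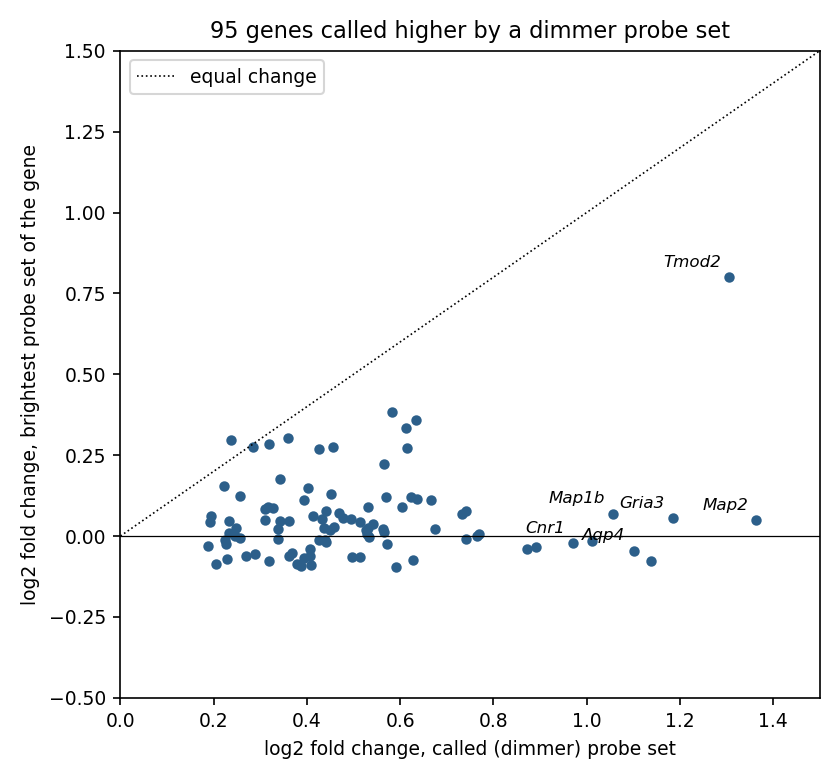
Log2 fold change (learning minus control) of the called, dimmer probe set (horizontal) and of the brightest probe set of the same gene (vertical) for 95 genes, 1 point per gene. The dotted line marks equal change. Most points lie near 0 on the vertical axis, with a median of 0.03 against 0.44 for the called probe sets, and Tmod2 stands apart at 0.80.

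The balance between probe sets of the same gene differed between the groups beyond the called genes. Over 350 genes whose tested probe sets lay at least 2 log2 units apart, picked without regard to fold change, the dimmest minus the brightest probe set averaged -3.42 ± 0.11 in control and -3.25 ± 0.03 in learning arrays (n = 7 each, two-sided exact permutation p = 5.83e-04, the smallest the 3432 assignments can give). The difference of 0.17 is a shift between arrays and no ratio of abundances, since probe sets differ in affinity. Within groups this balance followed the hexokinase 3'/5' ratio across the 14 arrays (Pearson r = -0.92, permutation p = 0.00681, adjusted p = 0.0272; Spearman rho = -0.73, permutation p = 0.0191, adjusted p = 0.0765), and r was -0.81 without the 2 arrays farthest from the median. For the actin ratio r was -0.85 (permutation p = 0.0151, adjusted p = 0.0303; rho = -0.62, permutation p = 0.0413, adjusted p = 0.0825), and it was -0.49 without the 2 farthest arrays. For the Gapdh ratio r was -0.61 (adjusted p = 0.125; rho = -0.09, permutation p = 0.756, adjusted p = 0.756), and for the spike-in level -0.35 (adjusted p = 0.156; rho = -0.27, permutation p = 0.321, adjusted p = 0.428), these 4 being all that were computed. The first principal component held 26.5% of the variance and separated the groups (exact permutation p = 5.83e-04).

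Signs of RNA quality and of neighbouring tissue also differed in part between the groups, by two-sided exact permutation tests not adjusted for their number. The Gapdh 3'/5' ratio was 0.45 ± 0.05 (log2) in learning and 0.51 ± 0.06 in control arrays (exact p = 0.0443), while the hexokinase ratio (1.30 ± 0.05 against 1.53 ± 0.49, exact p = 0.281) and the actin ratio (1.31 ± 0.03 against 1.36 ± 0.15, exact p = 0.460) did not pass. Control replicate 5 had the highest 3'/5' ratio of all arrays for each of the 3 control genes. Spike-in probe sets were 0.20 brighter in the learning group (exact p = 0.00524). Dentate granule markers averaged -0.16 (exact p = 0.0449), microglial markers -0.14 (exact p = 0.0437) and 5 choroid plexus markers -0.57 (exact p = 0.00117). The last mean was carried mostly by Ttr (-2.09), and the other 4 averaged -0.20, with -0.70 for Igfbp2. A wider set of 14 such markers without Ttr averaged -0.06 (exact p = 0.0664), but 10 of them lay below the dim filter.

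**Figure D3:**
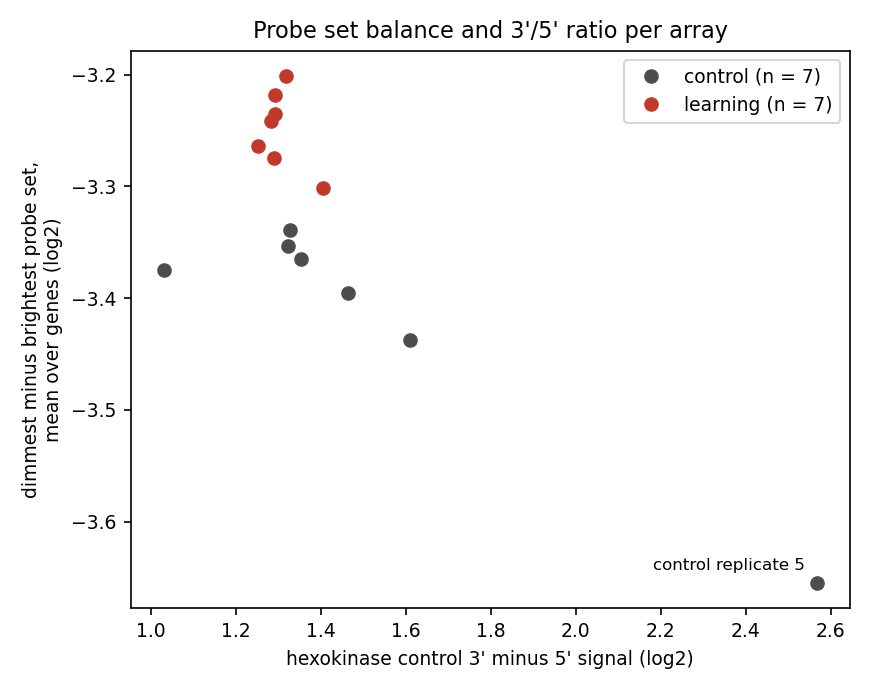
Mean difference between the dimmest and the brightest probe set over 350 genes (vertical, log2) against the 3' minus 5' signal of the hexokinase control probe sets (horizontal, log2), 1 point per array, 7 per group. All learning arrays lie above all control arrays, at -3.25 ± 0.03 against -3.42 ± 0.11, and control replicate 5 lies apart at the lower right.

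Genes of synaptic transmission were higher as groups in the learning animals. Camera compares a list with the other genes, and the median log2 fold change over all genes at their brightest probe sets was -0.03. List values near 0 thus lie above that of a typical gene, and negative ones lie less far below it than below 0. Of 14 measured glutamate receptor genes, Gria1 (0.66, 1.58-fold, adjusted p = 0.00323) and Grin2a rose at their brightest probe sets and 12 did not pass there, Gria3 among them, which rose at a dimmer one. Others that did not pass were Grm7 (0.36, adjusted p = 0.0692), Grin2c (-0.11) and Gria2 (0.08). The list passed with a mean of 0.20 and a median of 0.07, and its mean over the 13 members other than Grin2a was 0.10 (camera adjusted p = 8.00e-04, 0.0286 with an estimated correlation, 3 members higher adjusted over the list alone). Of 13 genes of GABA receptors and signalling, Gabra4 (0.81, adjusted p = 0.00323) and Gabrg1 rose at their brightest probe sets and 11 did not pass, with 0.76 for Gad2, 0.13 for Gabra5 and -0.03 for Gabbr1. The mean of that list was 0.17 and its median -0.01 (camera adjusted p = 0.0392, and adjusted p = 0.0703 with an estimated correlation), and 4 members were higher adjusted over the list alone. With the probe set balance as covariate, which differed by 0.17 between the groups, neither list passed (adjusted p = 0.177 for both), with means of 0.11 and 0.12. Over 33 alternatives the adjusted p ran from 2.17e-04 to 0.177 for glutamate receptors, passing in 32. It ran from 0.0011 to 0.825 for the GABA list, passing in 24, and that list was not called without control replicate 4 (0.0621) or 6 (0.0769) or learning replicate 4 (0.0627) or 7 (0.0514).

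Of 33 voltage-gated channel genes, 4 rose at their brightest probe sets: the potassium channel subunits Kcnab1 (0.45, adjusted p = 0.00323), Kcnq3 (0.71, adjusted p = 0.0366) and Kcnip4 (0.44, adjusted p = 0.0440), and the calcium channel Cacna1a (0.68, adjusted p = 0.0140). The remaining 29 did not pass there, though Kcnd2 rose at a dimmer probe set (0.61, adjusted p = 0.0062), and the brightest, Kcnip2 (-0.05) and Kcnab2 (0.00041), were nearly level. The list's mean was 0.15 (camera adjusted p = 7.46e-05, 0.0136 with an estimated correlation, and over the list alone 9 higher and 1 lower). Its call held with the probe set balance as covariate (mean 0.11, adjusted p = 0.00816). It was lost only with a dim filter at the 60th percentile (mean 0.03, adjusted p = 0.115), over 33 alternatives whose lowest adjusted p was 9.49e-06. With that filter the GABA list had a mean of -0.02 and the glutamate receptor list a mean of 0.079 (adjusted p = 0.0397).

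Of 28 neuronal adhesion genes, 5 rose at their brightest probe sets: the postsynaptic neuroligin Nlgn1 (0.50, adjusted p = 0.00323), Cntn1 (0.70, adjusted p = 0.00925), the ephrin receptors Epha5 (0.36) and Epha4 (0.21), and Lsamp (0.57, adjusted p = 0.0469), a member called outside the rule. The other 23 did not pass there, among them Nptn (0.06) and Ctnnb1 (0.08), and Cdh2 rose at a dimmer probe set (0.32, adjusted p = 0.0200). The list mean was 0.11 (camera adjusted p = 7.46e-05, 0.0345 with an estimated correlation, 7 higher and 1 lower adjusted over the list alone). Over 33 alternatives its adjusted p ran from 2.29e-05 to 0.260, and only the probe set balance as covariate ended its call (mean 0.05).

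Presynaptic release genes were higher as a list, by small amounts and not in every member. Of 30 genes 24 had a fold change above 0 and 6 below, Syt11, a vesicle protein, rose at its brightest probe set (0.57, adjusted p = 0.0430), and 29 did not pass there, with 0.38 for Sv2b, which rose at another (0.58, adjusted p = 0.00453), 0.17 for Syn1, 0.12 for Snap25, 0.04 for Dnm1 and -0.13 for Sncb. The list passed with a mean of 0.16 (camera adjusted p = 7.72e-09, 0.0136 with an estimated correlation), and 11 members were higher and 1 lower adjusted over the list alone. Of 23 postsynaptic density scaffold genes 0 passed in limma at their brightest probe set and 16 had a fold change above 0, among them Sipa1l1 (0.30, adjusted p = 0.0585), Cnksr2 (0.22), Kalrn (0.51), Cask (0.26), Shank3 (0.05) and Dlgap1 (0.0072), and 3 were higher adjusted over the list alone. Cnksr2 rose at another probe set (0.56, adjusted p = 0.00231). That list had a mean of 0.09 (camera adjusted p = 6.55e-04, and adjusted p = 0.0558 with an estimated correlation). With the probe set balance as covariate the adjusted p was 0.177 for release genes (mean 0.04) and 0.309 for scaffolds (mean 0.02), the highest of 33 alternatives for each. The lowest were 7.95e-10 and 1.51e-05, and the scaffold list was also not called with the Gapdh ratio as covariate (adjusted p = 0.0578).

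Among 39 kinases and phosphatases of synaptic plasticity, Camk2a, the calcium-dependent kinase of the postsynapse, rose 1.69-fold (10.17 ± 0.26 against 9.41 ± 0.35, adjusted p = 0.0150), and so did Prkca (0.72, adjusted p = 0.0209). At their brightest probe sets the other 37 did not pass, with 0.78 for Camk4, 0.12 for Prkar1a, 0.07 for Ppp3ca and 0.08 for Ppp3r1. Ppp3r1 rose at a dimmer probe set (0.74, adjusted p = 0.0423), and so did Ppp3cb (0.41, adjusted p = 0.00581). The list mean was 0.09 (camera adjusted p = 0.00145, 0.0136 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone. With the probe set balance as covariate the mean was 0.07 (camera adjusted p = 0.177). Camk2a was called at 2 of its 3 probe sets and had 0.04 at the third. Over 33 alternatives the list's adjusted p ran from 6.96e-04 to 0.177, passing in 32.

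Of 38 genes of G proteins and RGS proteins, Gnao1 (0.54, adjusted p = 0.0166), Gnai1 (0.41, adjusted p = 0.0201) and the phospholipase Plcb1 (0.18, adjusted p = 0.0302) rose at their brightest probe sets, and 35 did not pass, Pde1a (0.42), Gnas (0.09) and Gnb1 (0.0022) among them. The list passed with a mean of 0.05 (camera adjusted p = 0.0114) but not with an estimated correlation (adjusted p = 0.0632), and its mean was -0.05 with the probe set balance as covariate (adjusted p = 0.747). Of 42 genes of neurite growth and the cytoskeleton, the kinesin Kif3a (0.30, adjusted p = 0.0301), the neurofilament Nefl (0.24, adjusted p = 0.0333) and Pfn2 (0.15, adjusted p = 0.0444) rose at their brightest probe sets, and 39 did not pass there, with -0.17 for Stmn4, 0.0088 for Mapt and 0.11 for Actg1. Map2, Map1b and Ina (0.46, adjusted p = 0.0233) are among the 39 and rose only at dimmer probe sets. The cytoskeleton list's mean was 0.01 (camera adjusted p = 0.0180, adjusted p = 0.0558 with an estimated correlation), and 0.02 with the probe set balance as covariate (adjusted p = 0.177). Adjusted over the list alone, 4 genes of the former and 3 of the latter were higher. Of 33 alternatives the G protein list passed in 24, with adjusted p-values from 0.00568 to 0.747 (0.0501 without control replicate 5), and the cytoskeleton list in 29, from 5.84e-04 to 0.177. With fry neither passed (adjusted p = 0.176 and 0.155).

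Ribosomal protein genes were lower as a group, by small amounts. Of 39 measured, Rpl5 (-0.22, adjusted p = 0.0209), Rpl34 (-0.14), Rpl4 (-0.17), Rpl11 (-0.21) and, called outside the rule, Rpl18 (-0.16) fell, and 34 did not pass, Rps29 (-0.08) and Rpl3 (-0.15) among them. Only 2 of the 39 had a fold change above 0, and 20 were lower adjusted over the list alone. The list mean was -0.10 (camera adjusted p = 9.81e-10, and adjusted p = 0.139 with an estimated correlation, which was 0.37). With the preset correlation of 0.01 it also passed with the probe set balance as covariate (mean -0.07, camera adjusted p = 6.94e-05). That covariate was not run with the estimated correlation. Of 68 genes of the respiratory chain and ATP synthase, Ndufv1 (-0.23, adjusted p = 0.0128) and Atp5mf (-0.19, adjusted p = 0.0493) fell and 66 did not pass, with -0.12 for Ndufb10, -0.17 for Atp5pf, -0.0035 for Atp5mc3 and 0.0090 for Cox4i1. That mean was -0.06 (camera adjusted p = 7.46e-05, adjusted p = 0.242 with an estimated correlation), and 1 member was lower adjusted over the list alone. With the probe set balance as covariate the respiratory mean was -0.02 (camera adjusted p = 0.260). Over 33 alternatives the adjusted p of ribosomal genes ran from 6.00e-14 to 0.139, that of respiratory genes from 2.65e-08 to 0.260, and the means of both stayed below 0.

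**Figure D4:**
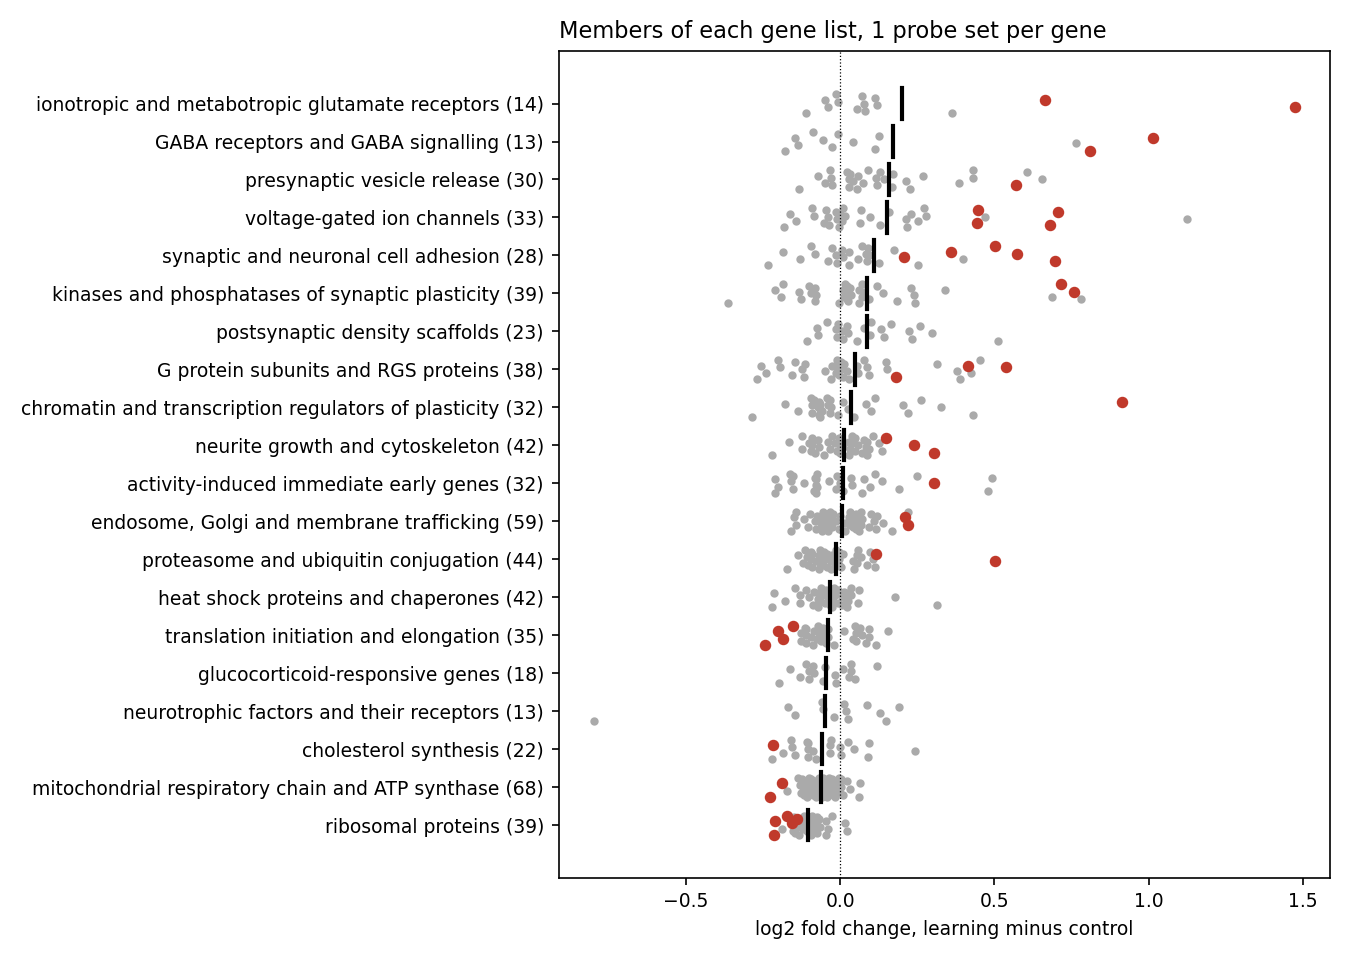
Log2 fold changes (learning minus control) of the members of 20 gene lists, 1 point per gene at its brightest probe set, with the number of measured members in brackets. Red points passed the test over all probe sets, grey points did not, and the black bar is the list mean. The means run from 0.20 for glutamate receptors to -0.10 for ribosomal proteins.

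Most immediate early genes, which neuronal activity switches on within minutes, did not pass the test, and the list had no common direction. Arc was 8.06 ± 0.12 in learning and 8.02 ± 0.09 in control animals (log2 fold change 0.03, adjusted p = 0.782), Fos had -0.20 (adjusted p = 0.451), Egr1 -0.08 (adjusted p = 0.493), Junb -0.21 (adjusted p = 0.157) and Nr4a1 -0.15 (adjusted p = 0.387). Of 32 members, Nr4a3, an orphan nuclear receptor, rose (0.30, SE 0.08, adjusted p = 0.0421), and 31 did not pass at their brightest probe sets, with 0.49 for Nr4a2 (adjusted p = 0.0788), -0.15 for Egr2, 0.48 for Syt4, -0.16 for Scg2 and 0.10 for Nrn1. The list had a mean of 0.0095 and a median of -0.02 and did not pass (camera adjusted p = 0.552, direction upward, 1 member higher adjusted over the list alone, and 0.177 to 0.948 over 33 alternatives). At an unadjusted p under 0.05 there were 8 members, 4 higher and 4 lower. Members such as Nr4a3, Nr4a2, Syt4 and Homer1 were above, and Egr2, Scg2, Junb and Dusp1 below, the control mean in all 7 learning animals. By fry's test for change in either direction the list passed (limma, adjusted p = 3.26e-05), as did 18 of the 20 pathway lists in all. Homer1 did not pass at its brightest probe set (0.11, adjusted p = 0.339), but 1 of its other 4 probe sets did (0.67, adjusted p = 0.00593). Bdnf had 0.25 (adjusted p = 0.296), Dusp1 -0.12 (adjusted p = 0.242), the glucocorticoid targets Sgk1 0.05 (adjusted p = 0.887) and Fkbp5 -0.05 (adjusted p = 0.792), and Grin1 -0.0082 (adjusted p = 0.943). Grin2b lay below the dim filter, at a mean of 3.39, and was not tested.

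The other 8 pathway lists did not pass. Their camera adjusted p-values were 0.305 for translation initiation and elongation, in which Eif3b (-0.24), Eif6 (-0.18), Eif3k (-0.20) and Eif4b (-0.15) fell, and 0.842 for proteasome and ubiquitin genes, in which Skp1 (0.12) and Nedd4 (0.50) rose. They were 0.177 for membrane trafficking (Rab2a 0.22 and Vti1a 0.21 rose), 0.563 for chromatin regulators (Atf2 rose), 0.552 for cholesterol synthesis (Fads1 fell, -0.22), 0.585 for heat shock proteins, 0.702 for glucocorticoid-responsive genes and 0.449 for neurotrophic factors. At probe sets other than the brightest, and outside the rule, Ube2g1 and Usp9x of the proteasome list, Canx of the heat shock list, Gdi2, Rab10, Rab5a and Rab6a of the trafficking list and Smarca4 and Tcf4 of the chromatin list also rose. Mean and median had opposite signs for chromatin regulators (0.04 and -0.04), trafficking (0.0044 and -0.01) and neurotrophic factors (-0.05 and 0.01), for which camera's direction was upward, as for the other 2. With fry the translation list was lower (adjusted p = 0.00814), and with the mean of all probe sets per gene the trafficking list was higher (adjusted p = 0.00136).

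No cell marker list passed with camera (0 of 11 past the adjusted threshold, 4 at an unadjusted p under 0.05, 0 with fry's test for 1 direction and, by its test for either direction, the interneuron list). Median log2 fold changes were 0.07 for CA3 pyramidal neurons (Bok 0.01, Prss23 0.12), -0.08 for CA1 (Itpka -0.08, Mpped1 -0.11) and -0.08 for CA2 (Pcp4 -0.10, Ptpn5 -0.08). They were -0.20 for dentate granule cells (Btg1 -0.09, Stxbp6 -0.29), -0.10 for GABAergic interneurons (Cck -0.13, Gad1 -0.14) and -0.08 for other forebrain neurons (Pde10a 0.31, Ppp1r1b -0.08). Glial medians were -0.07 for astrocytes (Cst3 -0.06, Apoe -0.10), -0.08 for oligodendrocytes (Mbp 0.01, Mobp -0.07) and -0.11 for microglia (Ctss 0.0034, Csf1r -0.09). The median was -0.04 for vascular cells (Cldn5 -0.05, Slc2a1 -0.25) and -0.07 for choroid plexus and ependyma (Enpp2 -0.03, Igfbp2 -0.70). The CA1 list had a mean of -0.02 though camera's direction was upward. Up to 3 marker lists passed under some alternatives. With a dim filter at the 60th percentile, dentate, interneuron and astrocyte markers were lower (adjusted p = 0.0351 for each), and without control replicate 5 microglial markers were lower (adjusted p = 0.0223), as were astrocyte markers (adjusted p = 0.0454). With the probe set balance as covariate, astrocyte (mean -0.12, adjusted p = 2.26e-04), microglial (-0.19, adjusted p = 0.00143) and CA1 markers (-0.22, adjusted p = 0.0357) were lower. These calls used the preset correlation of 0.01. The correlation estimated in the main comparison was 0.27 for astrocyte, 0.28 for microglial and 0.34 for CA1 markers. With it their camera adjusted p there was 0.862, 0.801 and 0.920, and the covariate was not run with it. CA3 markers passed in 4 of 33 alternatives. They were higher with the Gapdh ratio as covariate (adjusted p = 0.0412, the lowest) and without control replicate 6 (adjusted p = 0.0456) or learning replicate 3 (adjusted p = 0.0434). Dentate markers were lower without control replicate 6 (adjusted p = 0.0456). Of their members at the brightest probe set, Spock1 of the CA3 list rose (0.28) and Ttr of the choroid list fell. At other probe sets, the astrocyte genes Aqp4, Gja1 and Slc1a3 rose.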

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

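The tests of single probe sets within a gene and of glial markers were chosen only after the results were seen, as were the hexokinase and actin ratios and the probe set balance as covariates and the use of 1 brightest probe set per gene. In 20 of 158 groups of 7 arrays, 1 array lay far from the others (gap over range above Dixon's critical value), where chance gives about 1 in 20 groups, and genes and lists share arrays. Control replicate 5 accounted for 6 of them: low Cnr1 (5.87) and Wdr7 (5.01), a high Gapdh 3'/5' ratio (0.638) and hexokinase ratio (2.57), and low means of postsynaptic scaffolds (7.47) and of G proteins (7.36). Other control arrays stood apart in Tmem47 (replicate 1, 9.54), Txnip (replicate 7, 6.94), the spike-in level (replicate 6, 8.73), kinases and phosphatases (replicate 2, 8.70), neurotrophic factors (replicate 3, 7.48), heat shock proteins (replicate 7, 9.03), glucocorticoid-responsive genes (replicate 3, 8.31) and trafficking genes (replicate 4, 9.09). In the learning group these were Gria3 (replicate 4, 6.91), Mtmr10 (replicate 2, 6.81), Arc (replicate 1, 7.81), Homer1 (replicate 6, 8.98), ribosomal proteins (replicate 4, 11.19) and proteasome genes (replicate 2, 9.46). The 18 spike-in probe sets, which measure no rat transcript, were 0.203 higher in the learning arrays (two-sided exact permutation p = 0.00524).

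Most called probe sets were higher in the learning group (243 against 76, but 84 against 48 with 1 brightest probe set per gene), and many belonged to genes whose brightest probe set hardly moved. A larger share of neurons stays open. Glial markers had a median of -0.0847 over 50 genes (quartiles -0.13 and -0.04), against 0.44 for the probe sets called higher. The former were read at the brightest probe set of each gene, and the latter were picked for their change and were often dimmer ones. In 95 genes called at a dimmer probe set the brightest had a median of 0.03, so the comparison decides little. With the probe set balance as covariate, astrocyte (-0.12) and microglial (-0.19) markers were lower, beside a median of 0.24 for the probe sets called higher. Both marker calls rest on the preset correlation of 0.01, and neither list passed in the main comparison. A change of signal at 1 probe set rather than of the whole transcript would leave the brightest probe sets little of the called change. Their share was 0.0571 (95% interval 0.0219 to 0.117). That interval was taken over the 95 genes, which were read on the same arrays, so it holds no spread between animals. The called probe sets were picked for their change, which by itself lowers the share, so its size is uncertain. Probe position, amplification length and isoform use cannot be told apart, because probe positions were not used here. RNA integrity stays open. With the Gapdh ratio as covariate the median change of the probe sets called higher went from 0.44 to 0.38, a share of 0.870 (jackknife SE 0.197). Their median SE went from 0.0894 to 0.10, and 39 probe sets were past the threshold. The shares were 0.901 with the hexokinase ratio, 0.929 with the actin ratio and 0.910 without control replicate 5. The hexokinase and actin ratios correlated only weakly with group (-0.32 and -0.25), so their shares decide little. Leaving out 1 array cannot remove a difference that the other arrays share. An array-wide trend of dimmer against brighter probe sets also stays open, since 0.557 of the change (jackknife SE 0.269, from 0.41 to 0.23 over 188 probe sets) was kept with a covariate that separates the groups, and learning itself remains an untested biological explanation.

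Ttr was 4.25-fold lower in the learning group, with all 7 animals below the control mean. It did not rest on 1 control array, since without control replicate 2, the highest, 0.879 of the log2 change was kept (-1.83, adjusted p = 0.0199). Carry-over of choroid plexus in dissection cannot be told apart from regulation in CA3. Within groups Ttr correlated with the mean of 14 other choroid and ependymal markers at r = 0.519 (permutation p = 0.133; rho = 0.332, permutation p = 0.288; r = 0.242 without the 2 farthest arrays), and the mean's difference between learning and control was -0.06 (two-sided exact permutation p = 0.0664). Of the 14, 10 lay below the dim filter and the mean followed mostly Igfbp2 (control SD 0.83, difference -0.70), so this test decides little.

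Synaptic lists were higher and the ribosomal list lower, a pairing that an axis of RNA integrity might also give, but with an estimated correlation only 5 lists passed, all higher, and the ribosomal (adjusted p = 0.139), GABA (0.0703) and scaffold (0.0558) lists did not. Across 6836 genes, which are not independent replicates, the profile of control replicate 5 against controls 1 to 3 correlated with learning minus controls 4, 6 and 7 at -0.131. Single other controls gave -0.20 to 0.22, so the value cannot be told apart from the spread between control arrays. Along the profile of control replicate 5, release genes (-0.17), G proteins (-0.16), scaffolds (-0.11) and glutamate receptors (-0.10) were lower and respiratory genes higher (0.09). Voltage-gated channels (-0.05), adhesion (-0.03), GABA (-0.02), cytoskeleton (0.03), kinase (0.04) and ribosomal genes (0.0069) moved less. These values come from a single array and have no spread, so they do not decide whether such an axis gives the pairing. Encoding of the new place remains open and untested against an axis of RNA integrity. The design varies it together with the cues and the movement of the platform, and these cannot be told apart.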

How the results depend on the processing

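Leaving out 3 arrays, the hexokinase, actin and spike-in covariates, the balance of dimmer and brighter probe sets as covariate and 1 brightest probe set per gene were chosen only after the data were seen. Of the values for named genes and gene lists under all alternatives, 3677 stayed on their side of the threshold, 569 lost and 61 gained a call, and 10 reversed. A reversal was counted only for genes and lists called in the main comparison, so uncalled ones among the 3677 may have changed sign. The mean of the immediate early gene list did, from 0.0095 to -0.05 with the probe set balance as covariate.

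The 319 probe sets past the adjusted threshold became 158 without a filter on dim probe sets, 39 with the Gapdh 3'/5' ratio as covariate, 3 with the dentate marker level, 177 with the hexokinase ratio, 143 with the spike-in level and 0 with the balance of dimmer and brighter probe sets. They became 105 without 3 arrays that stood apart and 132 with 1 brightest probe set per gene, where fewer arrays or genes were tested. Under the other alternatives for the whole comparison the count stayed within 1.5 times. The 555 at unadjusted p under 0.005 became 307 (Gapdh), 197 (dentate), 344 (without 3 arrays), 333 (brightest probe set) and 109 (balance). The 1898 at p under 0.05 became 1045 (dentate) and 853 (balance). The 11 pathway lists became 5 with an estimated correlation and 2 with the balance. Cell marker lists, 0 at first, became 3 with a dim filter at the 60th percentile, 2 with the Gapdh ratio, 3 with the dentate level, 2 without 3 arrays, 2 with the hexokinase ratio, 3 with the spike-in level and 3 with the balance. The cause was not tested for these.

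With each array left out the counts ran from 163 to 352 (adjusted threshold), 439 to 576 (p under 0.005), 1625 to 1941 (p under 0.05), 10 to 11 (pathway lists) and 0 to 2 (marker lists). The first was 163 without control replicate 1, 166 without 2 and 167 without 3, and 188, 164, 171 and 188 without learning replicates 3, 4, 6 and 7.

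Other probe sets reversed the sign for Ddx6 (-0.076), Aqp4 (-0.045), Mgll (-0.016), Cnr1 (-0.022), Zranb2 (-0.034), Adarb1 (-0.040), Clic4 (0.13 and 0.40) and Bnip3l (0.035), and the G protein list had a mean of -0.052 with the balance as covariate. None of these passed, and the cause was not tested. Whether the replicate numbers pair the samples was not settled. Of 7 pairs of equal number 2 correlated above 0.1, and the mean correlation was 0.016 for equal and -0.0031 for other numbers. With the number as a block 313 probe sets passed, 239 of them among the 319. The median SE of the probe sets called higher went from 0.0894 to 0.0711 with that block. Signal over background limits the dim probe sets, 6346 of which were not tested.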

Other observations

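The comparison of brightest with other probe sets was chosen only after the results were seen, and the counts over other divisions of the arrays before. Of 100 divisions of the 14 arrays into 7 and 7, the real one included, 1 gave as many probe sets past the adjusted threshold as the real groups (319, highest other 1). Since 1 of 100 is the lowest that this draw can give, chance is unlikely for that count but not excluded. For unadjusted p under 0.05, 1 of 100 reached the real count (1898, highest other 1391), and for p under 0.005, 1 of 100 (555, highest other 246). Chance is unlikely for both but likewise not excluded. For gene lists past the threshold with the preset correlation, 6 of 100 reached the real 11 (highest other 11), and chance cannot be excluded. With an estimated correlation 2 of 100 reached the real 5 (highest other 5), so a count as large was rare but was also given by 1 other division.

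Among genes with several tested probe sets, 942 in all, 3.72% of the brightest and 9.47% of the other probe sets were called higher (two-sided Fisher's exact test, p = 1.76e-07). In the other direction, 0.743% of the brightest and 0.0885% of the other probe sets were called lower, a difference that was not tested. The probe sets of 1 gene are not independent. Called probe sets were picked for their change, which by itself lowers the average change of the others beside theirs. In 30 genes called higher by their brightest probe set the next brightest had a median of 0.10 against 0.35. Of 133 genes with a call and more than 1 probe set, 84 had all probe sets in 1 direction, and 0 had calls in both directions.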
